A study of Homo sapiens with 8 samples.

How the data were processed

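RNA sequencing was done on KG1a cells treated for 48 h with vehicle (DMSO), 5 µM TAK-981, 1 µM venetoclax or both, 2 libraries per group. The group of each library was taken from the submitters' labels. RNA was prepared with a miRNeasy kit and sequenced as single reads, per the labels' protocols. The sources differ on the library method: the series design text names ribosomal RNA depletion, and the labels' protocols name a SMART-Seq low-input kit, a type of kit that generally primes on poly(A). The method decides how RNAs without poly(A) tails, such as histone mRNAs and small nuclear RNAs, are captured, so their values carry that limit.

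The deposited values are counts of reads per gene, whole numbers not normalized, in a table of 25168 genes with hg38 coordinates. Trimmomatic, STAR 2.6.0, HTSeq 0.11.1 and edgeR are named without role or order, per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Near-identical genes (histones, tryptases, 7SL RNAs, HLA genes) and overlapping genes are therefore uncertain, since their reads could be shared or dropped. The table holds no gene encoded in the mitochondrial genome.

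Counts were tested with edgeR's quasi-likelihood F test (R 4.3.3, edgeR 4.0.16, limma 3.58.1), with TMM scaling, edgeR's filterByExpr by group, which left 12843 genes, robust dispersion and 1 fit over the 8 libraries with a mean per group. Each contrast was tested two-sided, with Benjamini-Hochberg adjustment over the 12843 genes and a threshold of 0.05. All adjusted p-values of genes come from this test unless another tool is named, and fold changes are log2 values of its fit, at edgeR's default prior count. Each SE of a fold change was derived from the test, as the absolute log2 fold change over the square root of F. It is therefore an approximate value and not a fitted standard error. A prior count of 2 was used only for log2 CPM, as in the list tests, principal components and comparisons of single libraries. The comparisons were each drug with vehicle, the combination with vehicle and with each drug, and the interaction, which is the effect of TAK-981 with venetoclax less its effect without. Of 45 gene lists, 41 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01, adjusted over 41 lists, and again with a correlation estimated from the residuals. None of the list calls held with the estimated correlation (0 of 41 in each comparison). The lists of MHC class II genes and of erythroid, stromal and mitochondrially encoded genes had too few tested members. Of 1355 distinct list members, 1332 matched the table, 71 of them by an older name.

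The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes, per comparison of 2 groups, the 6 largest rises and 6 largest falls among called genes of at least 5 CPM on average whose groups do not overlap, and up to 5 per direction for the interaction. It adds up to 4 called members of each described list with the smallest p, and a fixed set of drug target, apoptosis and marker genes, and leaves out symbols with the form of unnamed or noncoding models, a filter that the noncoding OLMALINC passes. Some single-gene results that the rule takes are not reported here. A fold against a group with 0 counts was bounded with a floor of 3 counts over the group, and against 1 to 3 counts it is given with an exact 95% interval. Intervals and floors cover counting error only.

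Totals ran from 13204588 to 26304900 counts. The test was checked on simulated counts for these genes. The simulation gave all 8 libraries the same dispersion per gene, without the wider spread of the venetoclax libraries. Only genes of at least 5 CPM were drawn to be changed, so recovery below that is unknown. For TAK-981 against vehicle the test recovered 44% of 100 genes changed 1.5-fold and 91% of 100 changed 2-fold. It made 20 false calls, 11% of its calls, which include members of the shifted list below. For the interaction it recovered 8% and 59%, with 6 false calls (8.2%). In the simulated TAK-981 comparison a list shifted by 0.5 log2 units was called by camera, also with an estimated correlation (adjusted p = 0.00114). This was the respiratory chain list of 74 genes, and the simulated genes were drawn independently of each other. It therefore cannot show whether lists of correlated genes, or shorter lists, can be called with an estimated correlation. Alternatives were DESeq2's size factors, no filter on low counts, a mean of at least 1 CPM, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom, a test against a fold change of 1.5, the 4 libraries of a comparison alone and the estimated correlation. Leaving out both venetoclax libraries was added after seeing the data.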

Results

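RNA sequencing measured gene expression in KG1a, an established human acute myeloid leukemia cell line of immature, CD34-positive phenotype. Cells were treated for 48 h with vehicle, with 5 µM TAK-981, with 1 µM venetoclax or with both drugs. TAK-981 inhibits the enzyme that activates SUMO, a small protein attached to other proteins, and venetoclax inhibits BCL2, a protein that blocks apoptosis. Each of the 4 groups held 2 libraries, 8 in all. The total count per library was 22777546 and 23819348 for vehicle, 22995342 and 18161522 for TAK-981, 14667378 and 26304900 for venetoclax, and 20636292 and 13204588 for the combination. No label says that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

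The 4 groups separated on the first 2 principal components of log2 CPM, which held 53.8% and 22.5% of the variance. The third component, with 10.7%, placed venetoclax replicate 1 at -30.8 and venetoclax replicate 2 at 20.9. Over 9858 genes of at least 5 CPM, the replicates of a group differed by a median of 0.0968 log2 units for vehicle, 0.088 for TAK-981, 0.101 for the combination and 0.262 for venetoclax. In the venetoclax group 281 of these genes differed by more than 2-fold between replicates, against 9, 1 and 4 in the vehicle, TAK-981 and combination groups. The test pooled the spread over the 4 groups, so this difference entered every comparison. The pooled spread was smaller than that of the venetoclax libraries and larger than that of the others. Comparisons with the venetoclax group thus met too small a spread, and the others too large a one. With the 4 libraries of a comparison alone, calls fell from 2676 to 200 for venetoclax against vehicle. For the combination against venetoclax they fell from 5086 to 2497, and in the others they rose. Counts of calls therefore cannot be ranked across comparisons.

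**Figure D1:**
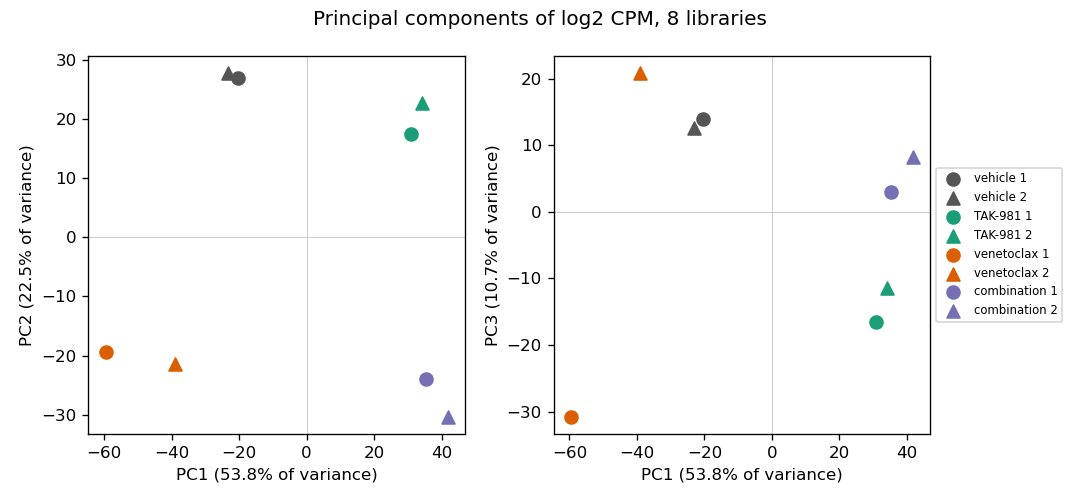
Each point is 1 of the 8 libraries, with PC1 on the horizontal axis of both panels, PC2 on the left vertical axis and PC3 on the right, as scores of log2 CPM. Colours give the group and shapes the replicate, and the venetoclax libraries lie at -30.8 and 20.9 on PC3.

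TAK-981 alone was compared with vehicle to give its own effect. The largest rises belonged to COL5A1, a chain of type V collagen (chromosome 9, 134641774 to 134844843, hg38), UNC13A, which primes synaptic vesicles, NFATC1, a calcium-regulated transcription factor, MYH15, a myosin heavy chain, MRC1, the macrophage mannose receptor, and BTN1A1, a butyrophilin. COL5A1 had 3 counts in the 2 vehicle libraries and 802 in the 2 TAK-981 libraries, a ratio of 296 (95% counting interval 101 to 1440). The log2 fold changes of the others were UNC13A 7.08, NFATC1 5.86, MYH15 5.35, MRC1 3.90 and BTN1A1 3.57. The largest falls were those of the kinase MINK1 -2.18, the signalling adaptor PIK3AP1 -2.16, the metalloproteinase MMP7 -2.01, the mitochondrial alanine aminotransferase GPT2 -1.82, the homeobox gene UNCX -1.81 and the Wnt-pathway transcription factor LEF1 -1.77. Of 12843 genes tested, 1562 passed, 768 higher and 794 lower, and among them 393 rose and 113 fell by more than 2-fold.

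Genes of DNA replication fell with TAK-981, with 36 of 45 lower, 1 higher and 8 not called (42 adjusted over the list alone; adjusted p = 6.94e-23, and adjusted p = 0.392 with an estimated correlation). Among them were the replicative helicase genes MCM6, MCM3, GINS1 and GINS2, with log2 fold changes of -0.89, -0.82, -0.84 and -1.07. Of 53 mitosis genes, 25 fell and 28 were not called (36 adjusted over the list alone; adjusted p = 6.36e-17, and adjusted p = 0.529 with an estimated correlation), among them the kinases CDK1 -0.99 and AURKA -0.73. Of 39 genes of DNA repair and checkpoints, 20 fell and 19 were not called (26 adjusted over the list alone; adjusted p = 2.07e-15, and adjusted p = 0.392 with an estimated correlation), with RAD51AP1 -0.96, FANCI -0.94 and the checkpoint kinase CHEK1 -0.91. Of 25 cholesterol synthesis genes, 11 fell, among them FDPS -0.81 and FDFT1 -0.75, while INSIG1, which restrains that pathway, rose by 3.48 (19 adjusted over the list alone; adjusted p = 1.01e-05, and adjusted p = 0.392 with an estimated correlation). Of 40 MYC targets, MYC alone was called, at -0.66 (SE 0.147, adjusted p = 0.0201), with 0 adjusted over the list alone, and the list's median was -0.20 (adjusted p = 0.00389, and adjusted p = 0.392 with an estimated correlation).

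Myeloid differentiation genes rose with TAK-981 in 5 of 15 cases (5 adjusted over the list alone; adjusted p = 0.0109, and adjusted p = 0.529 with an estimated correlation), among them the integrin ITGAM 2.26, the Fc receptor chain FCER1G 3.21 and CD33 2.22. MPO, the granule peroxidase, had 0 counts in vehicle and 23 in the TAK-981 libraries, at least 8.49-fold higher against a floor of 3 counts over the group. Markers of endothelial cells rose in 5 of 8 cases (5 adjusted over the list alone; adjusted p = 0.00673, and adjusted p = 0.478 with an estimated correlation), with the angiopoietin receptor TEK 2.94 and the endoglin gene ENG 1.10. Markers of mast cells and basophils rose in 4 of 7 (5 adjusted over the list alone; adjusted p = 0.00906, and adjusted p = 0.392 with an estimated correlation), with the carboxypeptidase CPA3 1.31 and the transcription factor GATA2 0.77. TPSAB1 and TPSB2, near-identical tryptase genes whose reads could be shared, had 2 counts each in vehicle and 35 and 49 with TAK-981, ratios of 19.4 (95% counting interval 4.98 to 166) and 27.1 (7.12 to 230). Of 48 interferon-stimulated genes, 6 rose, among them PARP9 0.54, and 1 fell, CMPK2 -0.99 (7 adjusted over the list alone; adjusted p = 0.0195, and adjusted p = 0.956 with an estimated correlation). Of 19 genes of MHC class I presentation, HLA-B 1.16, HLA-E 0.67 and HLA-C 0.69 rose (4 adjusted over the list alone; adjusted p = 0.00653, and adjusted p = 0.678 with an estimated correlation). In the unfolded protein response list 4 of 24 rose, with the chaperone HSPA5 0.63 (6 adjusted over the list alone; adjusted p = 0.00653, and adjusted p = 0.571 with an estimated correlation). Of 34 autophagy and lysosome genes 4 rose, with CTSB 0.66 (5 adjusted over the list alone; adjusted p = 0.00653, and adjusted p = 0.728 with an estimated correlation). Calls ended for the interferon-stimulated list without vehicle replicate 1 (median 0.28). Of the genes named here, BCL2L11, CD33, CHEK1, CTSB, ENG, FDFT1, GATA2, HLA-C, HLA-E, HSPA5, MYC, PARP9, SUMO3 and UBA2 were not called without at least 1 of the 8 libraries, and kept their direction. The count of changed genes was 376 and 389 without vehicle replicate 1 and 2, 375 and 341 without TAK-981 replicate 1 and 2, 3863 and 3851 without venetoclax replicate 1 and 2, and 61.4% to 72.1% of the calls without 1 vehicle or TAK-981 library were higher, against 49.2% with all 8. With the 4 libraries of the 2 groups alone it was 4096, and 1551 of the 1562 genes were among them.

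The effect of venetoclax alone was led by a fall of glycolysis and hypoxia-inducible genes. Of 30 such genes, 25 fell and 5 were not called (26 adjusted over the list alone; adjusted p = 7.98e-16, and adjusted p = 0.283 with an estimated correlation). They included PFKFB4, which sets the level of a glycolytic activator (chromosome 3, 48517684 to 48562015, hg38), at -3.65 (SE 0.515, adjusted p = 0.00348), the enolase ENO2 -2.79, PFKFB3 -1.37 and GPI -1.02. The list's median against the vehicle mean was -0.90 in venetoclax replicate 1 and -1.09 in replicate 2. Other large falls were those of the lectin gene SIGLEC6, -3.36, the TNF receptor adaptor TRAF1 -3.03, the creatine transporter SLC6A8 -2.87 and KANK3 -2.79. The largest rises were HIST1H4C 3.26, a replication-dependent histone gene, MX1 2.52 and IFI44L 1.61, both interferon-stimulated, MNS1 1.67, the ribosome assembly gene EBNA1BP2 1.67 and PLBD2 1.64. The replicates stood far apart for several of them. MX1 stood at 4.34 and 31.44 CPM in venetoclax replicates 1 and 2, IFI44L at 22.92 and 93.91, and PLBD2 at 169.5 and 51.12. Without venetoclax replicate 2 the log2 fold change was 0.43 for MX1 and 0.24 for IFI44L, neither then called, and -4.42 for JUN and 0.68 for OAS3. Without venetoclax replicate 1 it was 0.54 for PLBD2 and 1.09 for MNS1.

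Of 12843 genes, 2676 passed, 1463 higher and 1213 lower, with 132 and 363 past 2-fold. With the 4 libraries of the 2 groups alone it was 200, all among the 2676, and the balance turned, to 63 higher and 137 lower. Of the genes named here, BBC3, BCL2, BCL2L11, CD34, CDKN1A, HIST1H4C, IFI44L, JUN, KLF6, MNS1, MX1, OAS3 and PLBD2 were not called without at least 1 of the 8 libraries, and kept their direction. The count fell without any 1 of the vehicle, TAK-981 or combination libraries and rose without either venetoclax library. Fits without 1 venetoclax library take the spread from the remaining groups. They count the lone venetoclax library's own deviation as drug effect. The balance also turned without vehicle replicate 1, to 79 higher and 179 lower, and without vehicle replicate 2, to 236 higher and 297 lower.

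Of 31 proteasome subunits 20 rose with venetoclax (26 adjusted over the list alone; adjusted p = 1.27e-11, and adjusted p = 0.283 with an estimated correlation), with PSMD1 1.03 and PSMD7 0.89. Of 20 heat shock genes 12 rose (13 adjusted over the list alone; adjusted p = 1.11e-06, and adjusted p = 0.283 with an estimated correlation), with HSPH1 1.46 and DNAJA1 1.11. In the unfolded protein response list 11 of 24 rose, with HSPA5 1.39 and CALR 0.99, and EDEM1 -0.89 fell (15 adjusted over the list alone; adjusted p = 3.11e-05, and adjusted p = 0.283 with an estimated correlation). MYC targets rose in 20 of 40 cases and fell in 1 (25 adjusted over the list alone; adjusted p = 6.26e-09, and adjusted p = 0.0985 with an estimated correlation), with NOP16 1.00 and PA2G4 1.07. Replication genes rose in 18 of 45 cases and fell in 1 (23 adjusted over the list alone; adjusted p = 5.55e-06, and adjusted p = 0.452 with an estimated correlation). DNA repair genes rose in 9 of 39 and fell in 1 (13 adjusted over the list alone; adjusted p = 0.00523, and adjusted p = 0.538 with an estimated correlation). Mitosis genes rose in 6 of 53, a share near that of all genes (1463 of 12843), so this count shows no rise of the list. None passed when adjusted over the list alone. The list was called higher by camera (adjusted p = 0.000108, and adjusted p = 0.598 with an estimated correlation). Its median was 0.42 in venetoclax replicate 1 and 0.17 in replicate 2. Splicing genes rose in 17 of 44 cases and fell in 2 (22 adjusted over the list alone; adjusted p = 7.12e-06, and adjusted p = 0.283 with an estimated correlation). Respiratory chain genes rose in 20 of 74 (20 adjusted over the list alone; adjusted p = 8.81e-05, and adjusted p = 0.452 with an estimated correlation). Of 48 interferon-stimulated genes 15 rose (19 adjusted over the list alone; adjusted p = 0.000181, and adjusted p = 0.598 with an estimated correlation), with EIF2AK2 0.91 and OAS3 1.09, and the list's median was 0.10 in venetoclax replicate 1 and 0.65 in replicate 2.

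Of 20 NF-kB targets 8 fell with venetoclax (9 adjusted over the list alone; adjusted p = 0.00012, and adjusted p = 0.283 with an estimated correlation), with TNFAIP3 -1.30 and BIRC3 -0.89. Of 30 immediate early genes 8 fell and 1 rose (13 adjusted over the list alone; adjusted p = 0.000107, and adjusted p = 0.283 with an estimated correlation), with JUN -2.53 and KLF6 -0.73. Cholesterol genes fell in 10 of 25 cases (12 adjusted over the list alone; adjusted p = 0.000108, and adjusted p = 0.283 with an estimated correlation), with STARD4 -0.87 and SREBF2 -0.70. Lipid metabolism genes fell in 6 of 22 and rose in 1 (9 adjusted over the list alone; adjusted p = 0.0168, and adjusted p = 0.283 with an estimated correlation), with the cholesterol exporter ABCA1 -0.99. Of 19 MHC class I genes 5 fell, with HLA-E -0.97, and 1 rose, CALR (7 adjusted over the list alone; adjusted p = 0.0158, and adjusted p = 0.538 with an estimated correlation). Ribosomal protein genes fell in 13 of 74 cases (6 adjusted over the list alone; adjusted p = 0.000296, and adjusted p = 0.669 with an estimated correlation). Growth factor signalling genes fell in 4 of 21 (4 adjusted over the list alone; adjusted p = 0.000611, and adjusted p = 0.283 with an estimated correlation), with the kinase PIM1 -0.76. B cell markers fell in 3 of 6 (3 adjusted over the list alone; adjusted p = 0.0319, and adjusted p = 0.385 with an estimated correlation), with IGLL1 -1.41. Calls ended for the interferon-stimulated and B cell marker lists without venetoclax replicate 2 (medians 0.11 and -0.49) and the lipid metabolism and MHC class I lists without venetoclax replicate 1 (medians -0.21 and -0.32). They also ended for the ribosomal protein list without vehicle replicate 2 (median -0.042).

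The combination was compared with vehicle to give the joint effect of both drugs. COL5A1, UNC13A, NFATC1 and MYH15 were again among the largest rises, COL5A1 with 3 counts in vehicle and 1003 with the combination, a ratio of 436 (95% counting interval 149 to 2120). The log2 fold changes of the others were 7.70, 5.56 and 5.67. The thrombin receptor gene F2RL3 rose by 5.24 (SE 0.236, adjusted p = 8.24e-06), and HIST1H4C by 5.83 (SE 0.54, adjusted p = 0.000184). The largest falls were PFKFB4 -4.90, the vasodilator peptide gene ADM -3.71, the mitophagy gene BNIP3 -3.38, the collagen hydroxylase P4HA1 -2.99, ENO2 -2.97 and TRAF1 -2.96. In all, 3582 genes passed, 1647 higher and 1935 lower, with 662 and 394 past 2-fold.

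Glycolysis and hypoxia-inducible genes fell in 23 of 30 cases (25 adjusted over the list alone; adjusted p = 8.16e-14, and adjusted p = 0.524 with an estimated correlation). Cholesterol genes fell in 21 of 25 and rose in 1, INSIG1 (22 adjusted over the list alone; adjusted p = 1.61e-09, and adjusted p = 0.524 with an estimated correlation). Mitosis genes fell in 33 of 53 (40 adjusted over the list alone; adjusted p = 2.39e-12, and adjusted p = 0.524 with an estimated correlation), with CDK1 -1.25. DNA repair genes fell in 16 of 39 and rose in 1 (21 adjusted over the list alone; adjusted p = 2.62e-05, and adjusted p = 0.524 with an estimated correlation). Replication genes fell in 9 of 45 and rose in 2 (11 adjusted over the list alone; adjusted p = 0.00304, and adjusted p = 0.716 with an estimated correlation). Replication-dependent histone genes rose in 26 of 33 cases with a median of 2.41 (31 adjusted over the list alone; adjusted p = 2.39e-12, and adjusted p = 0.524 with an estimated correlation), with HIST1H1C 1.85. Their copies are near-identical, so reads could be shared between them. The noncoding RNAs chosen as signs of RNA quality moved the same way, 8 of 18 higher and 1 lower (10 adjusted over the list alone; adjusted p = 0.0111, and adjusted p = 0.524 with an estimated correlation), with RN7SK 4.57 and RN7SL1 4.69, both RNAs without poly(A) tails. Interferon-stimulated genes rose in 19 of 48 cases and fell in 1 (25 adjusted over the list alone; adjusted p = 1.8e-06, and adjusted p = 0.652 with an estimated correlation), with LGALS3BP 4.39. Lysosome and autophagy genes rose in 15 of 34 and fell in 1 (19 adjusted over the list alone; adjusted p = 1.47e-05, and adjusted p = 0.596 with an estimated correlation), with LAMP1 0.93. MHC class I genes rose in 7 of 19 (8 adjusted over the list alone; adjusted p = 0.00027, and adjusted p = 0.524 with an estimated correlation), with HLA-B 1.35.

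Proteasome genes rose with the combination in 15 of 31 cases (16 adjusted over the list alone; adjusted p = 1.8e-06, and adjusted p = 0.524 with an estimated correlation). Unfolded protein response genes rose in 10 of 24 (10 adjusted over the list alone; adjusted p = 0.00027, and adjusted p = 0.524 with an estimated correlation). Heat shock genes rose in 9 of 20 with 1 lower (10 adjusted over the list alone; adjusted p = 0.00975, and adjusted p = 0.596 with an estimated correlation). Of 74 respiratory chain genes 7 were higher and 1 lower (5 adjusted over the list alone). That is a smaller share higher than over all genes (1647 of 12843). The list was called higher by camera, with a median of 0.12 (adjusted p = 0.0305, and adjusted p = 0.716 with an estimated correlation). Megakaryocyte markers rose in 5 of 8 (6 adjusted over the list alone; adjusted p = 0.00311, and adjusted p = 0.524 with an estimated correlation), with the P-selectin gene SELP 2.33. Mast cell markers rose in 4 of 7 with 1 lower (6 adjusted over the list alone; adjusted p = 0.0111, and adjusted p = 0.524 with an estimated correlation). Endothelial markers rose in 5 of 8, with TEK 3.17, while PECAM1 -0.77 fell (8 adjusted over the list alone; adjusted p = 0.043, and adjusted p = 0.524 with an estimated correlation). Calls ended for the replication, endothelial and respiratory chain lists without combination replicate 2 (medians -0.14, 0.77 and 0.084) and the endothelial and respiratory chain lists without vehicle replicate 1 (medians 0.91 and 0.039). They also ended for the endothelial list without venetoclax replicate 1 (median 1.00) and the endothelial list without venetoclax replicate 2 (median 0.99). Of the genes named here, BCL2L1 and PECAM1 were not called without at least 1 of the 8 libraries, and kept their direction. The count of changed genes was 1766 and 1520 without vehicle replicate 1 and 2, 6121 and 6077 without venetoclax replicate 1 and 2, 1982 and 1424 without combination replicate 1 and 2. With the 4 libraries of the 2 groups alone it was 5740, with 3556 of the 3582 among them.

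**Figure D2:**
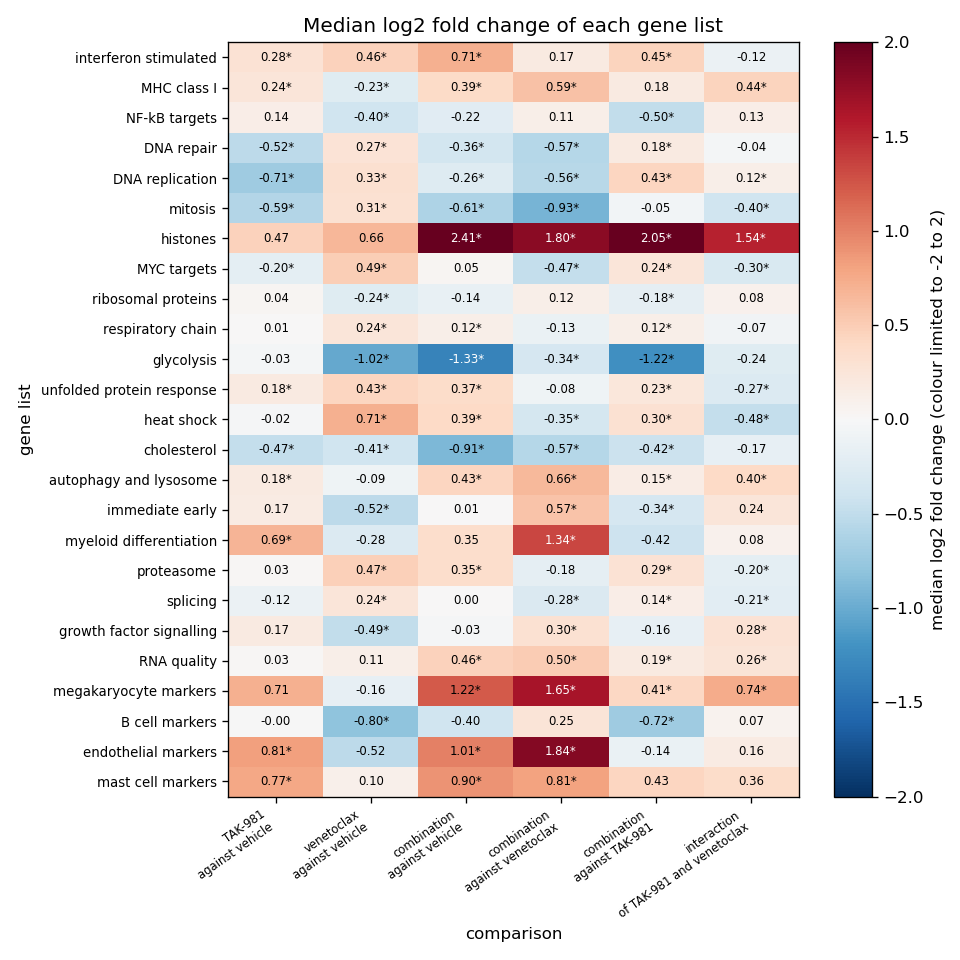
Rows are gene lists called in at least 2 comparisons and columns are the 6 comparisons, and each cell gives the median log2 fold change of the list's tested genes. An asterisk marks a list called with the preset correlation of 0.01, and the glycolysis row holds -1.02, -1.33 and -1.22 for venetoclax against vehicle, the combination against vehicle and the combination against TAK-981.

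The combination against venetoclax gives the effect of TAK-981 in cells that also received venetoclax. COL5A1 had 2 counts with venetoclax and 1003 with the combination, a ratio of 546 (95% counting interval 151 to 4520). Other large rises were UNC13A 7.67, NFATC1 6.83, F2RL3 5.19, MYH15 4.18 and MRC1 4.08. The largest falls were UNCX -2.32, the RNA polymerase III subunit POLR3G -2.31, LEF1 -2.27, NHS -2.18, the BMP antagonist NOG -2.04 and the noncoding OLMALINC -1.99. In all, 5086 genes passed, 2266 higher and 2820 lower, with 1126 and 343 past 2-fold.

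Mitosis genes fell in 47 of 53 cases (49 adjusted over the list alone; adjusted p = 4.77e-15, and adjusted p = 0.417 with an estimated correlation), with AURKA -1.12 and BUB1B -1.39. Replication genes fell in 29 of 45 with 1 higher (32 adjusted over the list alone; adjusted p = 6.95e-08, and adjusted p = 0.428 with an estimated correlation). DNA repair genes fell in 25 of 39 (26 adjusted over the list alone; adjusted p = 7.69e-08, and adjusted p = 0.417 with an estimated correlation). MYC targets fell in 22 of 40 cases and rose in 1 (24 adjusted over the list alone; adjusted p = 2.75e-05, and adjusted p = 0.304 with an estimated correlation). Splicing genes fell in 21 of 44 (21 adjusted over the list alone; adjusted p = 0.00132, and adjusted p = 0.417 with an estimated correlation). Heat shock genes fell in 12 of 20 and rose in 3 (15 adjusted over the list alone; adjusted p = 0.029, and adjusted p = 0.58 with an estimated correlation). Glycolysis genes fell in 13 of 30 and rose in 3 (18 adjusted over the list alone; adjusted p = 0.0496, and adjusted p = 0.711 with an estimated correlation). Cholesterol genes fell in 15 of 25 and rose in 2 (18 adjusted over the list alone; adjusted p = 0.000448, and adjusted p = 0.417 with an estimated correlation). MHC class I genes rose in 14 of 19 cases (14 adjusted over the list alone; adjusted p = 9.94e-06, and adjusted p = 0.417 with an estimated correlation), with HLA-B 2.29 and HLA-E 1.68. Lysosome genes rose in 21 of 34 and fell in 2 (28 adjusted over the list alone; adjusted p = 4.16e-06, and adjusted p = 0.428 with an estimated correlation), with GRN 1.65. Histone genes rose in 23 of 33 (25 adjusted over the list alone; adjusted p = 4.5e-08, and adjusted p = 0.428 with an estimated correlation). Of 18 RNA quality transcripts 8 rose beside them and 1 fell (10 adjusted over the list alone; adjusted p = 0.0131, and adjusted p = 0.417 with an estimated correlation).

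Myeloid differentiation genes rose in 7 of 15 cases against venetoclax (7 adjusted over the list alone; adjusted p = 0.0131, and adjusted p = 0.417 with an estimated correlation), with ITGAM 2.73 and CD33 2.30. Megakaryocyte markers rose in 7 of 8 (7 adjusted over the list alone; adjusted p = 0.00215, and adjusted p = 0.417 with an estimated correlation). Mast cell markers rose in 4 of 7 (4 adjusted over the list alone; adjusted p = 0.00399, and adjusted p = 0.417 with an estimated correlation). Endothelial markers rose in 6 of 8 with 1 lower (7 adjusted over the list alone; adjusted p = 0.00512, and adjusted p = 0.417 with an estimated correlation). Growth factor signalling genes rose in 10 of 21 (10 adjusted over the list alone; adjusted p = 0.00512, and adjusted p = 0.417 with an estimated correlation). Immediate early genes rose in 9 of 30 with 1 lower (10 adjusted over the list alone; adjusted p = 0.0273, and adjusted p = 0.417 with an estimated correlation). Calls ended for the immediate early, heat shock and RNA quality lists without venetoclax replicate 2 (medians 0.50, -0.41 and 0.39) and the glycolysis and heat shock lists without combination replicate 1 (medians -0.37 and -0.31). They also ended for the glycolysis list without combination replicate 2 (median -0.36) and the glycolysis list without vehicle replicate 1 (median -0.34). A further loss was that of the glycolysis list without vehicle replicate 2 (median -0.34) and the glycolysis list without venetoclax replicate 1 (median -0.31). Without venetoclax replicate 1 the log2 fold change of OLMALINC was -1.28, and that of UNC13A, which had 0 counts in the other venetoclax library, was 12.20, a fitted value and no bound. The count of changed genes was 2933 and 2369 without combination replicate 1 and 2. With the 4 libraries of the 2 groups alone it was 2497, with 2494 of the 5086 among them, and the balance turned, to 1342 higher and 1155 lower.

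The combination against TAK-981 gives the effect of venetoclax in cells that also received TAK-981. The largest rises were HIST1H4C 5.06, SIPA1L2 2.83, F2RL3 2.31, the tryptophanyl-tRNA synthetase WARS 2.21, WDR74 1.97 and SELP 1.76. WDR74 overlaps a small nuclear RNA gene whose reads could be counted with it. The largest falls were PFKFB4 -4.19, BNIP3 -3.88, SLC6A8 -2.79, ADM -2.75, P4HA1 -2.68 and TRAF1 -2.52. In all, 1130 genes passed, 355 higher and 775 lower, with 126 and 155 past 2-fold. Glycolysis genes fell in 24 of 30 cases (25 adjusted over the list alone; adjusted p = 5.59e-25, and adjusted p = 0.318 with an estimated correlation). Cholesterol genes fell in 12 of 25 (14 adjusted over the list alone; adjusted p = 3.15e-07, and adjusted p = 0.341 with an estimated correlation), with HMGCS1 -1.88. NF-kB targets fell in 6 of 20 (9 adjusted over the list alone; adjusted p = 0.00122, and adjusted p = 0.35 with an estimated correlation), with CXCL8 -2.25. Immediate early genes fell in 6 of 30 (7 adjusted over the list alone; adjusted p = 0.00409, and adjusted p = 0.341 with an estimated correlation).

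Histone genes rose in 20 of 33 cases (27 adjusted over the list alone; adjusted p = 5.3e-16, and adjusted p = 0.341 with an estimated correlation). Of 18 RNA quality transcripts 8 rose beside them (8 adjusted over the list alone; adjusted p = 0.00138, and adjusted p = 0.341 with an estimated correlation). Replication genes rose in 17 of 45 (31 adjusted over the list alone; adjusted p = 5.3e-16, and adjusted p = 0.341 with an estimated correlation), with CCNE1 0.87. DNA repair genes rose in 4 of 39 (12 adjusted over the list alone; adjusted p = 0.00205, and adjusted p = 0.538 with an estimated correlation). Proteasome genes rose in 8 of 31 (13 adjusted over the list alone; adjusted p = 3.54e-09, and adjusted p = 0.341 with an estimated correlation). Interferon-stimulated genes rose in 6 of 48 (10 adjusted over the list alone; adjusted p = 4.06e-06, and adjusted p = 0.538 with an estimated correlation). MYC targets rose in 3 of 40 with 1 lower (5 adjusted over the list alone; adjusted p = 0.000121, and adjusted p = 0.318 with an estimated correlation). Heat shock genes rose in 4 of 20 with 1 lower (9 adjusted over the list alone; adjusted p = 0.000283, and adjusted p = 0.438 with an estimated correlation). Lysosome genes rose in 4 of 34 with 1 lower (6 adjusted over the list alone; adjusted p = 0.00145, and adjusted p = 0.539 with an estimated correlation). Unfolded protein response genes rose in 4 of 24 with 1 lower (9 adjusted over the list alone; adjusted p = 0.00687, and adjusted p = 0.538 with an estimated correlation). Respiratory chain genes rose in 4 of 74 (0 adjusted over the list alone; adjusted p = 0.00138, and adjusted p = 0.538 with an estimated correlation). Of 25 NRF2 and ferroptosis genes 1 rose, NQO1 1.60, and 2 fell, SLC7A11 -1.20 and ACSL4 -0.49, while the list as a whole was called higher, with a median of 0.25 (3 adjusted over the list alone; adjusted p = 0.0362, and adjusted p = 0.592 with an estimated correlation). Stem cell genes fell in 3 of 38 cases (1 adjusted over the list alone; adjusted p = 0.0241, and adjusted p = 0.341 with an estimated correlation), with CLEC12A -1.13. B cell markers fell in 3 of 6 (3 adjusted over the list alone; adjusted p = 0.0484, and adjusted p = 0.498 with an estimated correlation). Of 44 splicing genes 1 rose and 1 fell, and the list was called higher, with a median of 0.14 (2 adjusted over the list alone; adjusted p = 0.0316, and adjusted p = 0.538 with an estimated correlation). Of 8 megakaryocyte markers 1 rose (2 adjusted over the list alone; adjusted p = 0.0484, and adjusted p = 0.467 with an estimated correlation). No ribosomal protein gene was called, and the list was called lower, with a median of -0.18, or -0.34 without combination replicate 2 (0 adjusted over the list alone; adjusted p = 0.00138, and adjusted p = 0.673 with an estimated correlation). Calls ended for the DNA repair, B cell marker, ribosomal protein, splicing and stem cell lists without combination replicate 1 (medians 0.082, -0.56, -0.050, 0.10 and -0.13) and the B cell marker, NRF2 and ferroptosis and splicing lists without TAK-981 replicate 2 (medians -0.76, 0.23 and 0.11). They also ended for the B cell marker and megakaryocyte lists without venetoclax replicate 1 (medians -0.72 and 0.41) and the B cell marker and megakaryocyte lists without venetoclax replicate 2 (medians -0.73 and 0.39). A further loss was that of the megakaryocyte list without TAK-981 replicate 1 (median 0.26) and the megakaryocyte and NRF2 and ferroptosis lists without combination replicate 2 (medians 0.25 and 0.21). The last was that of the megakaryocyte list without vehicle replicate 1 (median 0.40) and the megakaryocyte list without vehicle replicate 2 (median 0.41). Of the genes named here, ACSL4, ADM, BNIP3, CCNE1, CLEC12A, CXCL8, HMGCS1, NQO1, P4HA1, PFKFB4, SELP, SLC7A11 and WDR74 were not called without at least 1 of the 8 libraries, and kept their direction. The count of changed genes was 554 and 522 without vehicle replicate 1 and 2, 147 and 116 without TAK-981 replicate 1 and 2, 3683 and 3626 without venetoclax replicate 1 and 2, 241 and 41 without combination replicate 1 and 2. With the 4 libraries of the 2 groups alone it was 3746, with 1124 of the 1130 among them. Of those 3746 calls 45.8% were higher, against 31.4% of the 1130.

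The genes of the drugs' targets were read in every comparison. BCL2 (chromosome 18, 63123346 to 63320128, hg38), the target of venetoclax, stood at 294 ± 6.12 CPM in vehicle, 154 ± 5.33 CPM with TAK-981, 239 ± 4.27 CPM with venetoclax and 114 ± 7.12 CPM with the combination (SD, n = 2). It fell by 0.93 log2 units with TAK-981 (adjusted p = 0.000503), by 0.30 with venetoclax (adjusted p = 0.0497) and by 1.37 with the combination (adjusted p = 4.2e-05). UBA2, a subunit of the SUMO-activating enzyme, fell by 0.39 with TAK-981 (adjusted p = 0.0492) and by 0.61 with the combination (adjusted p = 0.00359), while its partner SAE1 had -0.34 (SE 0.116, adjusted p = 0.0924) with TAK-981. SUMO3 rose with TAK-981, 0.40 (SE 0.0942, adjusted p = 0.0255), and with the combination, 0.57 (SE 0.0944, adjusted p = 0.00257). MCL1, an apoptosis inhibitor linked to venetoclax resistance, had 0.019 (SE 0.0932, adjusted p = 0.902) with the combination, and BCL2L1 0.52 (SE 0.17, adjusted p = 0.0491). PMAIP1, which encodes the MCL1 antagonist NOXA, fell by 1.43 with the combination (adjusted p = 0.000244), against 0.18 (SE 0.135, adjusted p = 0.371) with venetoclax. BCL2L11, which encodes BIM, rose with TAK-981, 0.60 (SE 0.112, adjusted p = 0.0101), and fell with venetoclax, -0.57 (SE 0.116, adjusted p = 0.0111). CDKN1A, a cyclin-dependent kinase inhibitor, fell with venetoclax, -1.53 (SE 0.32, adjusted p = 0.0124), and so did BBC3, which encodes the apoptosis activator PUMA, -1.60 (SE 0.468, adjusted p = 0.0403). The interferon gene IFNB1 had 3, 1, 13 and 8 counts in the vehicle, TAK-981, venetoclax and combination groups and was not tested.

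**Figure D3:**
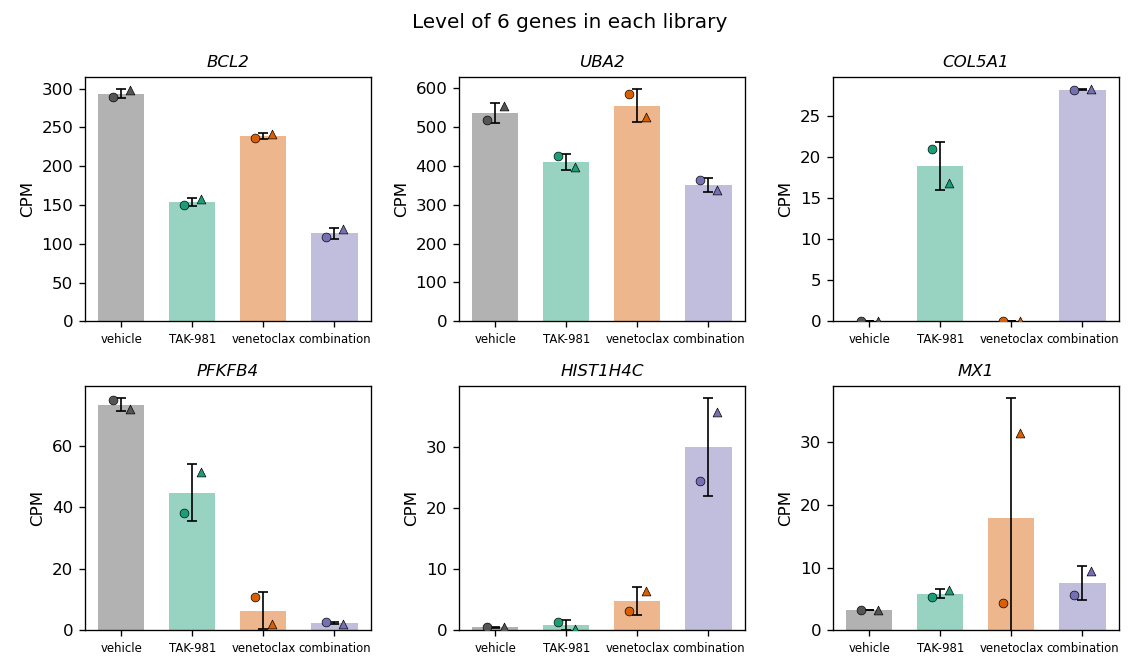
Bars give the mean CPM of the 2 libraries of each group, error bars the SD and points the libraries (circles replicate 1, triangles replicate 2), each panel on a linear axis from 0. BCL2 stands at 294 ± 6.12 CPM in vehicle and 114 ± 7.12 CPM with the combination, and the 2 venetoclax libraries stand apart for MX1, at 4.34 and 31.44 CPM.

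The interaction asks whether the effect of TAK-981 differs with venetoclax present. It was called in 4 of 12843 genes by edgeR's quasi-likelihood test, all higher, and 2427 genes had an unadjusted p under 0.05. The called genes were SIGLEC6, the Rab GTPase RAB37, the membrane-bending protein MTSS1 and the noncoding MIR4697HG, the last outside the rule for named genes and chosen after its value was seen. SIGLEC6 (chromosome 19, 51519525 to 51531856, hg38) had 3.81 (SE 0.42, adjusted p = 0.0385), and RAB37 1.42 (SE 0.146, adjusted p = 0.0385). TAK-981's change in SIGLEC6 was -0.46 without venetoclax and 3.35 with it, and in RAB37 1.61 and 3.03. The interaction was positive for histones (adjusted p = 9.53e-10, and adjusted p = 0.522 with an estimated correlation) and MHC class I genes (adjusted p = 4.23e-05, and adjusted p = 0.522 with an estimated correlation). It was also positive for lysosome genes (adjusted p = 0.000293, and adjusted p = 0.601 with an estimated correlation) and RNA quality transcripts (adjusted p = 0.00463, and adjusted p = 0.522 with an estimated correlation). So it was for growth factor signalling (adjusted p = 0.00916, and adjusted p = 0.522 with an estimated correlation) and megakaryocyte markers (adjusted p = 0.0221, and adjusted p = 0.522 with an estimated correlation). The last positive list was replication genes (adjusted p = 0.0331, and adjusted p = 0.71 with an estimated correlation). The interaction was negative for mitosis (adjusted p = 3.54e-05, and adjusted p = 0.626 with an estimated correlation) and MYC targets (adjusted p = 0.000752, and adjusted p = 0.522 with an estimated correlation). It was also negative for heat shock (adjusted p = 0.00134, and adjusted p = 0.522 with an estimated correlation) and splicing (adjusted p = 0.0038, and adjusted p = 0.522 with an estimated correlation). Further negative lists were the proteasome (adjusted p = 0.00463, and adjusted p = 0.601 with an estimated correlation) and the unfolded protein response (adjusted p = 0.0107, and adjusted p = 0.568 with an estimated correlation). The remaining negative lists were SUMO conjugation (adjusted p = 0.0216, and adjusted p = 0.522 with an estimated correlation) and the integrated stress response (adjusted p = 0.0311, and adjusted p = 0.661 with an estimated correlation). No member of these 15 lists was called over all genes. Adjusted over the list alone, 16 MYC targets, 8 stress response, 7 heat shock, 4 MHC class I, 3 RNA quality, 3 megakaryocyte, 2 proteasome and 1 unfolded protein response gene were, and 0 of the others. The 4 calls ended without any 1 of the vehicle, TAK-981 or combination libraries. Without either venetoclax library far more genes were called. Those fits take the spread from the remaining groups and count the lone venetoclax library's own deviation as drug effect. Their counts therefore do not measure the interaction. Calls ended for the integrated stress response and replication lists without TAK-981 replicate 2 (medians -0.27 and 0.084) and the integrated stress response and replication lists without combination replicate 1 (medians -0.26 and -0.029). They also ended for the integrated stress response, replication and megakaryocyte lists without vehicle replicate 1 (medians -0.25, 0.089 and 0.72) and the integrated stress response, replication, megakaryocyte, MYC target, RNA quality, proteasome and unfolded protein response lists without venetoclax replicate 2 (medians -0.088, 0.18, 0.91, -0.26, 0.31, -0.12 and -0.30). With no filter on low counts the number of genes called was 1098, 445 higher and 653 lower. With DESeq2 it was 300, 147 higher and 153 lower, and with the replicate number as a block 24, 17 higher and 7 lower. The count was 9 with limma-voom and 8 with DESeq2's size factors, of which 87.5% were higher against 100% with TMM.

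Across the 12843 genes, which are not independent replicates, TAK-981's change without venetoclax correlated with its change in cells with venetoclax (Pearson r = 0.76, or 0.374 with no filter on low counts), and these 2 comparisons share no library. Of the 768 genes higher with TAK-981, 644 were also higher in the combination against venetoclax, where independent lists give 136, and of the 794 lower, 621 were also lower, against 174. In the opposite direction 2 of the 768 and 2 of the 794 were called, against 169 and 140. All comparisons come from 1 fit with the same dispersion per gene. The values for independent lists here are therefore a reference and no null. Venetoclax's change without and with TAK-981 had r = 0.462, with 155 of 1463 genes higher in both (40.4 for independent lists) and 366 of 1213 lower in both (73.2); without venetoclax replicate 2 this r was 0.221, and with no filter 0.145. The changes with TAK-981 and with venetoclax, which share the vehicle libraries, had r = -0.0503. In 20 simulations all groups, vehicle included, were drawn unchanged from the vehicle means, in a spread that pools the 4 groups. There r averaged 0.475, and the covariance was -0.0215 observed against 0.0452 simulated. Unchanged groups that share controls correlate by construction, so the simulations give the size of that part only. They set no benchmark for genes that change. The spread of the 2 vehicle libraries alone adds a covariance of 0.0231, against -0.0224 observed on log2 CPM. Of the genes called with each drug, 45 were higher with both and 116 lower with both, where independent lists, which leave out the shared vehicle libraries, give 87.5 and 75. Another 153 were higher with TAK-981 and lower with venetoclax and 111 the reverse, against 72.5 and 90.4. Over all genes 45.8% had the same sign with both drugs. In the simulations it was 66.3%, a share that the shared vehicle libraries set where no gene changes. The r turned to 0.0777 without vehicle replicate 1 and 0.0847 without vehicle replicate 2 and to 0.262 with no filter, and 2 vehicle libraries are too few to split.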

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

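The tests named here were planned before the data were examined; MIR4697HG was named after its value was seen. The effect of TAK-981 differed with and without venetoclax, by the test of the interaction itself (edgeR quasi-likelihood, adjusted p = 0.0385 for each), in 4 genes. The interaction was 3.81 log2 units for SIGLEC6, 1.42 for RAB37, 1.34 for MIR4697HG and 1.14 for MTSS1. Mean CPM in the vehicle, TAK-981, venetoclax and combination groups was 8, 5.85, 0.77 and 8.04 for SIGLEC6, 54.3, 166, 22.7 and 186 for RAB37, 66.4, 74.1, 29.6 and 83.3 for MIR4697HG, and 47.7, 70.5, 43.9 and 143 for MTSS1. The 4 calls ended when any 1 of the vehicle, TAK-981 or combination libraries was left out. They stayed without either venetoclax library. Those fits take the spread from the remaining groups and count the lone venetoclax library's own deviation as drug effect.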

How the results depend on the processing

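The alternative without both venetoclax libraries was chosen after seeing the data; the others were planned. In the order TAK-981, venetoclax and the combination against vehicle, then the combination against venetoclax and against TAK-981, the 4 libraries of each comparison alone called 4096, 200, 5740, 2497 and 3746 genes. By construction these fits leave out the spread of the other 2 groups. A test against a fold change of 1.5 called 267, 91, 743, 1002 and 98, and 0 for the interaction by edgeR's glmTreat, where 422 genes had an unadjusted p under 0.05. Without both venetoclax libraries the counts were 3860 with TAK-981, 6112 with the combination against vehicle and 3671 against TAK-981. With 1 library left out, where a lone library was assumed to vary like the other groups, counts ran from 341 to 3863, 258 to 5365, 1424 to 6121, 2369 to 7185 and 41 to 3683 in the same order. For the interaction they ran from 0 to 4436. Without a filter on low counts the combination against TAK-981 gave 1875 genes and the interaction 1098, against 4 as planned; other interaction counts were 8 with DESeq2's size factors, 9 with limma-voom and 300 with DESeq2, and the cause was not tested.

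The replicate numbers are not known to pair libraries: deviations of same-numbered libraries correlated between -0.041 and 0.38 over the 6 pairs of groups. With the replicate number as a block the interaction gave 24 genes, and the counts of the other comparisons stayed within 1.5 times. With an estimated correlation 0 lists were called in each of the 6 comparisons. Without both venetoclax libraries as well it was 0 in the 3 comparisons that do not need them, and the cause was not tested. The correlation of TAK-981's change without and with venetoclax was 0.76, or 0.374 with no filter, and ran from 0.649 to 0.768 with 1 library left out. For venetoclax's change it was 0.462, or 0.145 with no filter, and ran from 0.221 to 0.522. The correlation of the 2 drugs' changes, -0.0503, reversed to 0.262 with no filter, was -0.104 at a mean of at least 1 CPM, and ran from -0.107 to 0.0847, with 0.0777 and 0.0847 without vehicle replicate 1 and 2; the cause was not tested. Of 2202 values of the 151 gene results under alternatives, 2028 kept direction and call, 163 lost the call, 10 gained one and 1 reversed: the change of MCL1, combination against vehicle, which was not called, went to -0.0199 without combination replicate 2 and ran up to 0.0487 with 1 library left out. Of 1423 values of the 102 called lists, 217 lost the call and 1 reversed, replication genes in the interaction, whose median ran from -0.0285 without combination replicate 1 to 0.22 without replicate 2. The lowest totals, 13204588 and 14667378 counts, lie in the combination and venetoclax groups and limit low-expressed genes there.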

Other observations

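The tests of depth, unequal response, S phase and a single library below were chosen after the result was seen. Those of GC content with length and of RNA without poly(A) tails were written before their results. The last of these was written with RN7SK and RN7SL1 already seen, and leaves both out. The following lists were called in none of the 6 comparisons. With the combination against vehicle the BCL2 family had 2 higher and 2 lower of 15 (3 adjusted over the list alone; adjusted p = 0.767). Caspases and death receptors had 3 higher and 4 lower of 26 (7 adjusted over the list alone; adjusted p = 0.914). Cyclin-dependent kinase inhibitors had 2 higher and 5 lower of 15 (8 adjusted over the list alone; adjusted p = 0.194). For p53 targets it was 5 higher and 7 lower of 27 (14 adjusted over the list alone; adjusted p = 0.914). Mitochondrial dynamics genes had 2 higher and 6 lower of 26 (8 adjusted over the list alone; adjusted p = 0.484). Interferon genes and sensors had 4 higher and 0 lower of 15 (4 adjusted over the list alone; adjusted p = 0.141). Immune ligands had 2 higher and 4 lower of 20 (6 adjusted over the list alone; adjusted p = 0.554). Chromatin repressors had 3 higher and 7 lower of 37 (10 adjusted over the list alone; adjusted p = 0.723). Germline genes had 1 higher and 1 lower of 8 (2 adjusted over the list alone; adjusted p = 0.664). Drug transporters had 3 higher and 3 lower of 16 (6 adjusted over the list alone; adjusted p = 0.554). Markers of T and NK cells had 2 higher and 2 lower of 9 (5 adjusted over the list alone; adjusted p = 0.484). Median, mean and test had 1 sign in all 102 called list tests and differed in 26 of 144 others, among them p53 targets, caspases and kinase inhibitors with the combination. PMAIP1 had an interaction of -1.52 (SE 0.197, adjusted p = 0.0598), short of the threshold. CD34, the stem cell surface marker, rose with venetoclax, 0.49 (SE 0.135, adjusted p = 0.0323), or 0.31 without venetoclax replicate 1, and its call ended without any 1 of the vehicle, TAK-981 or combination libraries.

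The venetoclax libraries differed by a median of 0.262 log2 units per gene. Thinned to the lowest total of the 8, they differed by 0.265, against at most 0.106 in the other groups, which argues against depth. After trends on GC content and gene length were removed the difference was 0.23, against at most 0.1, although these trends explained 22.8% of its variance. A response to venetoclax of unequal strength stays open: across genes the difference correlated with the change from TAK-981 to the combination at r = -0.283, between the bounds set for and against it. Venetoclax replicate 1 followed that change with r = 0.276 and replicate 2 with r = 0.651, and the labels give no batch to test.

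Histone genes rose with the combination by a median of 2.41 (95% bootstrap interval 1.87 to 3.41, 33 genes, and adjusted p = 0.524 by camera with an estimated correlation). The bootstrap intervals given here resample genes, which are not independent replicates, and hold no variation between libraries. Against vehicle the DNA replication list had a median of -0.261 (-0.312 to -0.151), and its call was lost with an estimated correlation. Without combination replicate 2 its median was -0.135 and its call ended, and without replicate 1 it was -0.406, both outside the interval. With TAK-981 alone the list's medians were -0.72 and -0.697 in the 2 libraries, where those of histones were 0.55 and 0.129. Replication genes thus fell there without a fall of histones. This list therefore cannot decide on more cells in S phase against vehicle, which stays open. Against TAK-981 more cells in S phase stays open, since replication genes rose there with the histones, by a median of 0.427 (0.356 to 0.48; adjusted p = 0.341 with an estimated correlation), or 0.278 without combination replicate 1. A larger share of RNA without poly(A) tails in these libraries may contribute. The 83 small RNAs tested had a median change of 0.742 (0.432 to 1.19), between the bounds set for and against it. Of them 25 were higher and 0 lower by edgeR. The 12 tested RNU genes, looked at after this result, were all higher, with a median of 4.13. They are part of the 83 and of the 25, so they add no separate evidence. Most of the SNORA and SNORD genes were not called. A biological rise and a change of RNA capture cannot be told apart here, since the 2 combination libraries carry both and the library method is stated in 2 ways.

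Glycolysis and hypoxia-inducible genes fell with venetoclax (adjusted p = 0.283 with an estimated correlation). After trends on GC content and length were removed the list's median was -0.946, against -1.03 over the same 26 of 30 genes, so 92.1% was kept. The fall was in both libraries, -0.9 and -1.09 against the vehicle mean, where the vehicle libraries differed by 0.131, and in both combination libraries against TAK-981, -1.32 and -1.18. A response of these genes to venetoclax itself and a difference in culture density or oxygen both stay open, and neither was tested.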
